A study of Mus musculus with 18 samples.

How the data were processed

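RNA was measured in 18 libraries from mice at P15, in 6 groups of 3. The Kcnq2 line gave cortex and hippocampus from Kcnq2 flox/flox::Emx1-Cre+ mice (cKO) and littermate controls (WT). The Scn1a line gave hippocampus from Scn1a A1783V/+::Slc32a1-Cre+ mice (A1783V) and controls (WT). Per the labels' protocols, total RNA was purified with a ZymoResearch kit, ribosomal RNA was removed with RiboZero, and libraries were made with the TruSeq Stranded Total RNA kit. Per the submitters' processing notes, reads were aligned with HISAT2 to mm10 (GRCm38). The quantifier, the annotation and the strand setting are not given in the sources used here, so a gene could not be told apart from an antisense or near-identical partner.

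The deposited values were TPM, transcripts per 1000000, with 1 value per gene symbol and library, for 38019 features, and each library's values were checked to add up to 1000000. Of these symbols, 36217 matched a gene name in GENCODE M21, which supplied biotypes, transcript lengths and GRCm38 coordinates. The design had been written for read counts. The deposited unit holds no counts, so the comparisons were made with limma on log values instead, and a second count test set in the design was not run. The scaling, the filter and the pseudocount of this fit were set once the unit was known.

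Each library received a scale factor, the mean log2 ratio to the mean of all libraries after trimming ratios by 0.3 at either end and levels by 0.05. A feature was tested when its scaled TPM reached 0.5 in at least 3 libraries. This left 15553 features, of which 12896 were protein coding, 400 were small RNAs and 576 had no GENCODE M21 name. The small RNA class includes ribosomal RNA, also that of mitochondria. Tests used log2(scaled TPM + 0.1), so a log2 difference of a weakly expressed gene understates its change. All 18 libraries entered 1 fit with a mean per group, 12 residual degrees of freedom, an intensity trend and robust moderation (limma 3.58.1, R 4.3.3). P-values were two-sided and adjusted by Benjamini-Hochberg over all features of a comparison, with a threshold of 0.05. They measure the spread between libraries, pooled over all groups. Where both tissues of the Kcnq2 line came from the same mice, these libraries are not independent mice.

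The comparisons were cKO against WT in cortex, cKO against WT in hippocampus, A1783V against WT in hippocampus, and a pair of differences between effects. The first difference was the Kcnq2 effect in cortex minus that in hippocampus. The second was the Kcnq2 effect minus the Scn1a effect in hippocampus.

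Gene lists were tested with camera of limma at a preset correlation of 0.01 between genes, adjusted over the 38 lists of a comparison, each with at least 4 tested members. The lists covered activity-regulated genes, channels and receptors, cell-type and tissue markers, metabolism and stress. They were written from general knowledge before the data were examined, as were the groups, the comparisons, the model formula and the alternatives other than those named below as added. Camera with a correlation estimated from the residuals and fry were run beside the preset one. Members were also adjusted over the list alone. A list's median is over its tested members.

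The text names genes by a rule set before the data were examined: Kcnq2, Scn1a, Emx1 and Slc32a1; up to 10 of the largest rises and falls past the threshold with a gene name and fully separated libraries; and up to 4 members of each list with the smallest p. Gm10020, Avp and Oxt fell outside it and were chosen after their values were seen. Xist and Ddx3y had been set for checks of the samples. Rn7s2, Rny1 and mt-Rnr2 also fell outside the rule and are named for library composition.

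Depth was estimated from the low values. For genes with 1 annotated transcript of at least 500 bases, a value divided by what 1 fragment is worth should be whole. The transcript length was taken less a fitted offset per library. Offset and step were chosen to make a score as large as possible. This score was the share of low values whole within 0.1, multiplied by the share above 1 fragment less 0.1. It reached 85.9 to 87.8%. For a step fixed beforehand chance gives a share of 20%, and a chance level for the fitted maximum was not worked out. By this estimate 1 fragment on a transcript of 2000 bases was worth 0.0187 to 0.0285 TPM in the Kcnq2 line and 0.00688 to 0.0124 TPM in the Scn1a line. The steps depend on transcript lengths chosen here, so counts were not rebuilt from them.

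The scripts were tested on simulated data made from the fitted means and spread, with genes changed by known folds. At a change of 2-fold the limma fit recovered 58.2% of changed genes in the cortex comparison (15327 genes in the simulated fit), 53.7% in the Kcnq2 hippocampus comparison (15335 genes) and 50% in the Scn1a comparison (15304 genes). At 1.5-fold these shares were 36.4%, 16.7% and 19.7%, and at 4-fold 90.9%, 90.9% and 92.3%. Unchanged genes called numbered 14, 7 and 6. For the difference between tissues, 4.48%, 21.2% and 68.8% were recovered at 1.5-fold, 2-fold and 4-fold. For the difference between lines these were 0%, 26.9% and 76.9%. In each of these differences 2 unchanged genes were called. Every simulation held 64 to 67 changed genes at each fold, and genes with large changes make the adjusted threshold easier to reach for the others. The real comparisons of mutant and control called 1, 0 and 3 genes. The shares recovered may therefore overstate what the real comparisons could find. With no change simulated, 0 of 38 lists were called in any comparison. The simulated noise was drawn for each gene on its own, so this count does not cover lists whose members vary together. Other divisions of the real libraries into 3 and 3 gave medians of 6, 7 and 11 called lists. These were for the cortex, Kcnq2 hippocampus and Scn1a comparisons.

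The alternatives were other scale factors (median of ratios, or none), no filter or a stricter one (scaled TPM of 1), pseudocounts of 0.01, 0.5 and 1, structural or small RNA left out, Xist or mt-Rnr2 as a covariate, removal of each library's trend on transcript length, moderation without robustness, the libraries of a comparison alone, a replicate block, and each library left out in turn. The pseudocounts, the unscaled values, small RNA, length and mt-Rnr2 settings were added after the data were examined, as were a relabelling with both Kcnq2 tissues of a replicate number together and 2 tests of sex by Ddx3y. Figures were drawn with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9. No library was left out.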

Results

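Total RNA was sequenced from the brain of mice at P15 in 18 libraries, in 6 groups of 3. The Kcnq2 line carried floxed alleles of the potassium channel gene Kcnq2 and an Emx1-Cre driver, which acts in cells of the dorsal forebrain. Cortex and hippocampus were taken from mice labelled cKO and littermate controls (WT). The Scn1a line carried the A1783V allele of the sodium channel gene Scn1a with a Slc32a1-Cre driver, which acts in inhibitory neurons. Hippocampus was taken from 3 mice labelled A1783V and 3 controls (WT). The series set out to compare these 2 ways in which hypersynchronous activity can begin. Values are scaled TPM with the SD over n = 3 libraries per group, and log2 differences are on log2(scaled TPM + 0.1).

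Each library held 21352 to 22812 features above 0. The low values gave an estimated 7.43M to 13M fragments on genes of at least 500 bases, with a median of 9.38M, where M stands for 1000000. Small RNA, counted here with ribosomal RNA such as the mitochondrial mt-Rnr2, took 72.0 to 80.0% of the TPM in the Kcnq2 line and 91.1 to 93.7% in the Scn1a line. Protein-coding genes other than the mitochondrially encoded ones took 15.3 to 21.6% and 3.88 to 5.95%. The signal recognition particle RNA Rn7s2 alone took 28.1 to 43.7% across all libraries. The scale factors were therefore 1.27 to 1.81 in the Kcnq2 line and 0.343 to 0.496 in the Scn1a line. Line and library composition could not be separated, and levels were compared within a line. Within a line, every mutant library also had a higher scale factor than every control of its tissue. The lowest mutant and highest control factors were 1.61 and 1.59 in cortex and 1.53 and 1.40 in Kcnq2 hippocampus. In the Scn1a line they were 0.446 and 0.405. Genotype and library composition therefore cannot be told apart within a line either. Libraries of a group correlated at 0.897 to 0.958, and no pair was identical. The first principal component held 32.8% of the variance and the second 11.6%.

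Tissue markers matched the labels of the Kcnq2 line. Hippocampus exceeded cortex by 0.60 (log2) over the dentate gyrus markers, 12 of 15 of which were higher, and by 0.99 over the hippocampal pyramidal markers, 15 of 19 of which were higher. Choroid plexus and ependymal markers were 2.10 higher in hippocampus. Striatum markers differed by −1.67.

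The targeted genes were not lower in the mutants with all libraries. Kcnq2 (chromosome 2, GRCm38, 181075579 to 181135300, minus strand) measured 21.5 ± 0.243 in WT cortex and 23.1 ± 1.35 in cKO cortex, and 20.6 ± 0.620 in WT and 26.0 ± 2.19 in cKO hippocampus. The log2 differences were 0.11 (limma adjusted p = 0.835) and 0.34 (limma adjusted p = 0.377). A value per gene also counts exons outside the deleted part, so it did not check the cKO labels, and these libraries are named by their labels. Scn1a (chromosome 2, 66270778 to 66440840, minus strand) measured 8.57 ± 2.61 in WT and 9.28 ± 0.732 in A1783V hippocampus (log2 difference 0.16, limma adjusted p = 0.762), which reversed to −0.11 without WT replicate 1. The A1783V allele changes a codon, which these values cannot show. In the Kcnq2 line the Scn1a difference was −0.24 in cortex (limma adjusted p = 0.762) and −0.31 in hippocampus (limma adjusted p = 0.611), and the Kcnq2 difference in the Scn1a line was 0.27 (limma adjusted p = 0.374). The driver gene Emx1 differed by 0.20 in cortex and 0.48 in hippocampus of the Kcnq2 line (limma adjusted p = 0.818 and 0.470). Slc32a1 differed by 0.45 in the Scn1a line (limma adjusted p = 0.485).

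**Figure D1:**
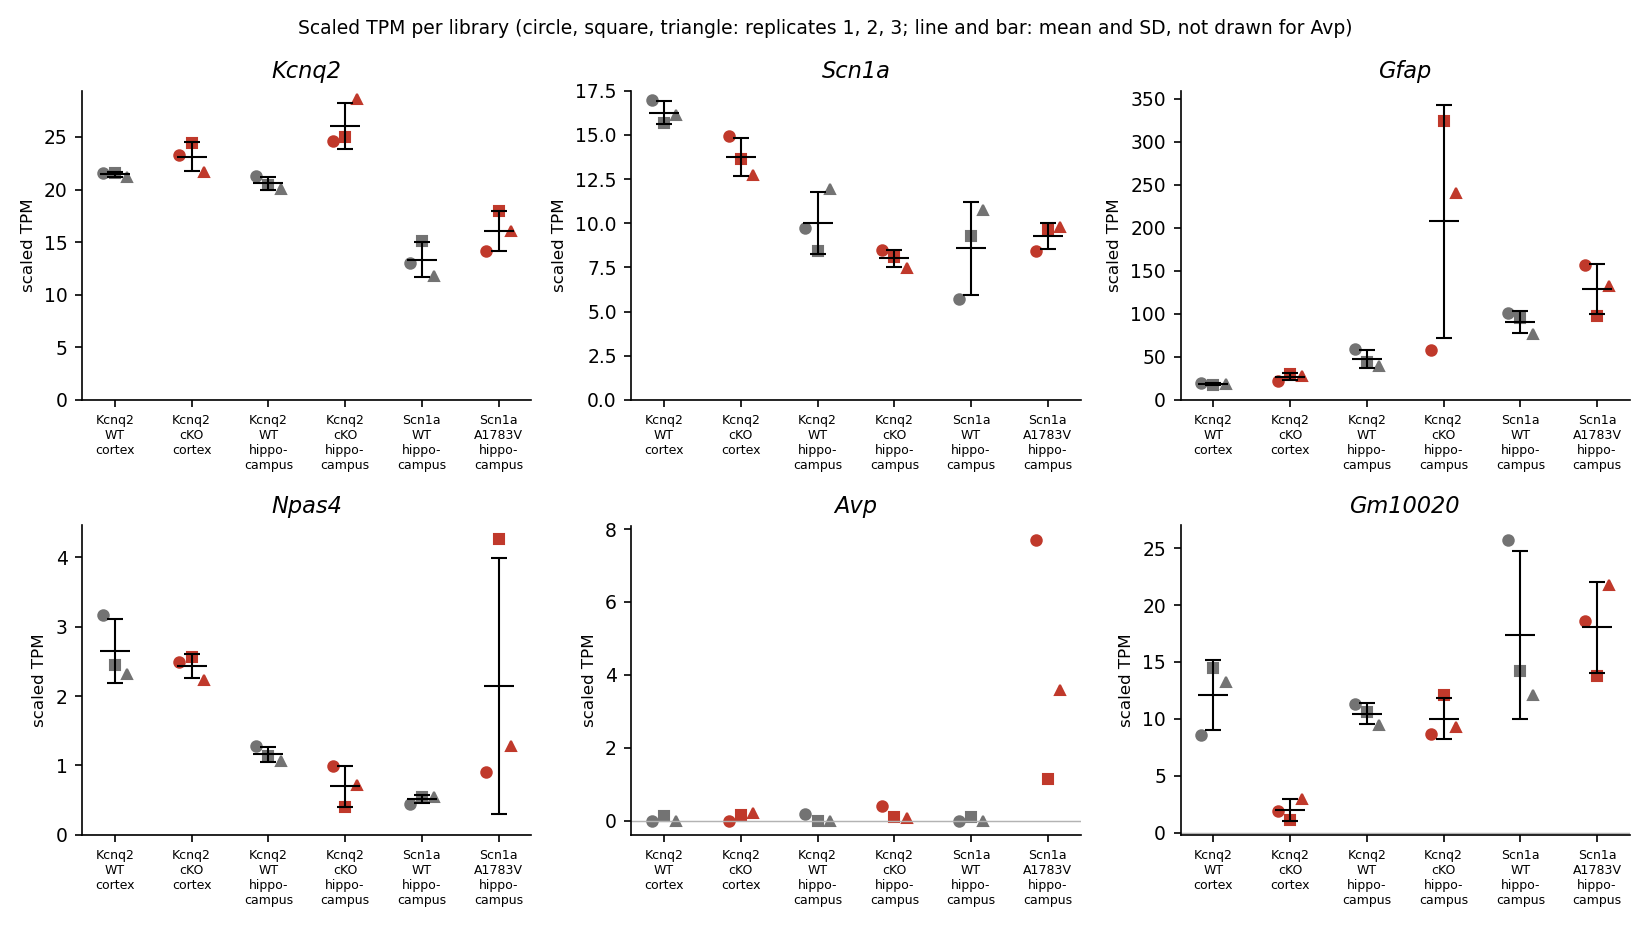
Scaled TPM (vertical axis) of Kcnq2, Scn1a, Gfap, Npas4, Avp and Gm10020 in each of the 18 libraries, by group; circles, squares and triangles are replicates 1, 2 and 3, and lines with bars are means and SDs, left out for Avp because some libraries are listed at 0. Kcnq2 lay at 24.6 to 28.6 in cKO hippocampus and 20.1 to 21.3 in WT hippocampus, and Gm10020 at 1.08 to 2.99 in cKO cortex and 8.60 to 14.4 in WT cortex.

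The cortex comparison asked how the cortex of mice labelled cKO differed from that of controls. Genes of myelin, of cholesterol synthesis and of the nuclear part of oxidative phosphorylation fell as lists. Mitochondrially encoded mRNAs, reactive astrocyte genes and choroid plexus markers rose as lists. None of these list calls held with an estimated correlation (smallest limma adjusted p = 0.933). No protein-coding gene passed the threshold over all genes.

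Limma called 1 gene of 15553, the processed pseudogene Gm10020 (chromosome 15, 52477617 to 52478228, minus strand), chosen for naming after its values were seen. It fell from 12.1 ± 3.08 in WT cortex to 2.0 ± 0.957 in cKO cortex (log2 difference −2.61, SE 0.32, limma adjusted p = 0.0084). Reads of a pseudogene cannot be told apart from those of a near-identical parent gene in these values. The Gm10020 call was lost without WT replicate 2, WT replicate 3 or cKO replicate 1 (limma adjusted p = 0.10, 0.101 and 0.0717). It was also lost with mt-Rnr2 as a covariate, with the replicate block and with the libraries of the comparison alone (limma adjusted p = 0.0854, 0.102 and 0.286), the last of which called 14 other genes. At an unadjusted p under 0.05, 434 genes were higher and 655 lower, 1089 in all, where chance gives 778. The libraries of WT and cKO were fully separated for 20.5% of genes, where chance gives 10%. Of the 38 lists, 6 passed the threshold in camera and 32 missed it. With an estimated correlation the smallest adjusted p of any list was 0.933, and fry called 0, so each of the 6 calls rests on the preset correlation.

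Every one of the 26 myelin and oligodendrocyte genes was lower in cKO cortex, by a median of −0.31 (limma camera adjusted p = 4.9e-07; adjusted p = 0.933 with an estimated correlation). Opalin measured 4.77 ± 0.689 in WT and 2.90 ± 0.528 in cKO, and Gjc2 4.10 ± 0.941 and 2.38 ± 0.346, and neither passed over the list alone. Cholesterol synthesis genes fell by a median of 0.25 (limma camera adjusted p = 2.4e-04; adjusted p = 0.933 with an estimated correlation), with 5 of 24 members positive and differences of −0.48 for Ebp, −0.45 for Msmo1 and −0.62 for Fdps.

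The 2 genomes that encode the respiratory chain moved apart in cortex. All 13 mitochondrially encoded mRNAs were higher in cKO, by a median of 0.42 (limma camera adjusted p = 4.9e-07; adjusted p = 0.933 with an estimated correlation), with 0.45 for mt-Nd4 and 0.46 for mt-Cytb. The mitochondrial ribosomal RNA mt-Rnr2 was higher too, at 9.15, 11.3 and 10.8% of the TPM in cKO cortex and 8.32, 8.99 and 5.39% in WT, and its libraries were also separated in hippocampus. Of 39 nuclear oxidative phosphorylation genes, 4 were positive, and the median was −0.24 (limma camera adjusted p = 6.7e-09; adjusted p = 0.933 with an estimated correlation). Cox7c fell from 57.1 ± 9.05 to 33.7 ± 6.06 and Cox7a2 from 65.6 ± 5.73 to 47.0 ± 7.13, both with limma adjusted p = 0.0487 adjusted over the list alone, and 11 of 15 other settings ended either call. With mt-Rnr2 as a covariate the medians fell to 0.15 for the mitochondrial list and −0.13 for the nuclear list (limma adjusted p = 0.000538 and 1.2e-05).

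Reactive astrocyte genes were higher in cKO cortex in 18 of 19 cases, by a median of 0.36 (limma camera adjusted p = 0.0282; adjusted p = 0.933 with an estimated correlation). Osmr differed by 0.91, Serpina3n by 0.69 (0.28 without cKO replicate 2) and Gfap by 0.53. Choroid plexus and ependymal markers were higher by 0.59 in 14 of 18 cases (limma camera adjusted p = 0.0088; adjusted p = 0.933 with an estimated correlation), led by Clic6 at 1.08. Their median ranged from 0.30 without WT replicate 3 to 0.93 without cKO replicate 3, and was 0.19 with pseudocount 1. Among glutamatergic neuron markers, which were not called as a list, Nrgn fell from 238.5 ± 34.6 to 164.3 ± 29.6 (log2 difference −0.54, limma adjusted p = 0.0484 adjusted over the list alone), a call that 8 of 15 other settings ended.

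The myelin, mitochondrial and oxidative phosphorylation calls held without any single cortex library, but the mitochondrial median fell to 0.23 without WT replicate 3, with mt-Nd4 and mt-Cytb at 0.22. Fdps was lower by 0.35 without WT replicate 3 and Ebp by 0.31 without cKO replicate 2, and with all libraries neither passed over the list alone. The cholesterol median was −0.14 without WT replicate 3. The reactive astrocyte call was lost without WT replicate 1, WT replicate 2 or cKO replicate 2 (limma adjusted p = 0.0927, 0.0591 and 0.143), the cholesterol call without WT replicate 3 (limma adjusted p = 0.131), the choroid plexus call without WT replicate 3, cKO replicate 1 or cKO replicate 2 (limma adjusted p = 0.155, 0.327 and 0.0920), and the Cox7a2, Cox7c and Nrgn calls without WT replicate 1, WT replicate 3, cKO replicate 2 or cKO replicate 3 (limma adjusted p from 0.135 to 0.382).

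The hippocampus comparison asked the same of the second tissue of the Kcnq2 line. Reactive astrocyte genes rose there as a list. Late activity-regulated genes also rose as a list, a call that was lost without cKO replicate 3. Choroid plexus and ependymal markers fell as a list, the opposite of their direction in cortex. None of these list calls held with an estimated correlation (smallest limma adjusted p = 0.441). Adjusted over their lists alone, the neuropeptide Npy rose and the GABA-A receptor genes Gabrd and Gabrg1 fell, with neither list called. Immediate early genes, which mark recent activity, did not pass the test.

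Over all genes limma called 0 of 15553 (smallest adjusted p = 0.205). At an unadjusted p under 0.05, 1495 genes differed, 755 higher and 740 lower, and 18.7% of genes had fully separated libraries, where chance gives 10%. Without cKO hippocampus replicate 1, limma called 198 genes, 117 higher and 81 lower. Of the 38 lists 10 passed in camera, 6 up and 4 down, and 28 missed the threshold. With an estimated correlation 0 passed, and fry called 0 in 1 direction and 4 in either direction.

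All 19 reactive astrocyte genes were higher in cKO hippocampus, by a median of 1.41 (limma camera adjusted p = 3.6e-17; adjusted p = 0.441 with an estimated correlation). Adjusted over the list alone, 15 of the 19 rose, and over all genes 0 did. Gfap (chromosome 11, 102887336 to 102900912, minus strand) rose from 47.4 ± 10.5 to 207.3 ± 135.9, and Serpina3n (chromosome 12, 104406729 to 104414329, plus strand) from 3.75 ± 0.620 to 21.5 ± 13.9, both with limma adjusted p = 0.00524 adjusted over the list alone. S100a10 rose from 4.21 ± 0.922 to 19.8 ± 11.4 (limma adjusted p = 0.00167 adjusted over the list alone), and Emp1 by 1.44 (limma adjusted p = 0.00484 adjusted over the list alone). The list mean was 0.17 above the controls in cKO replicate 1, 1.85 in replicate 2 and 2.38 in replicate 3. Without replicate 1 the median was 2.0, and without replicate 3 it was 1.07. The 20 astrocyte markers had a median of −0.09, with Aqp4 rising by 0.98 (limma adjusted p = 0.0391 adjusted over the list alone).

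**Figure D2:**
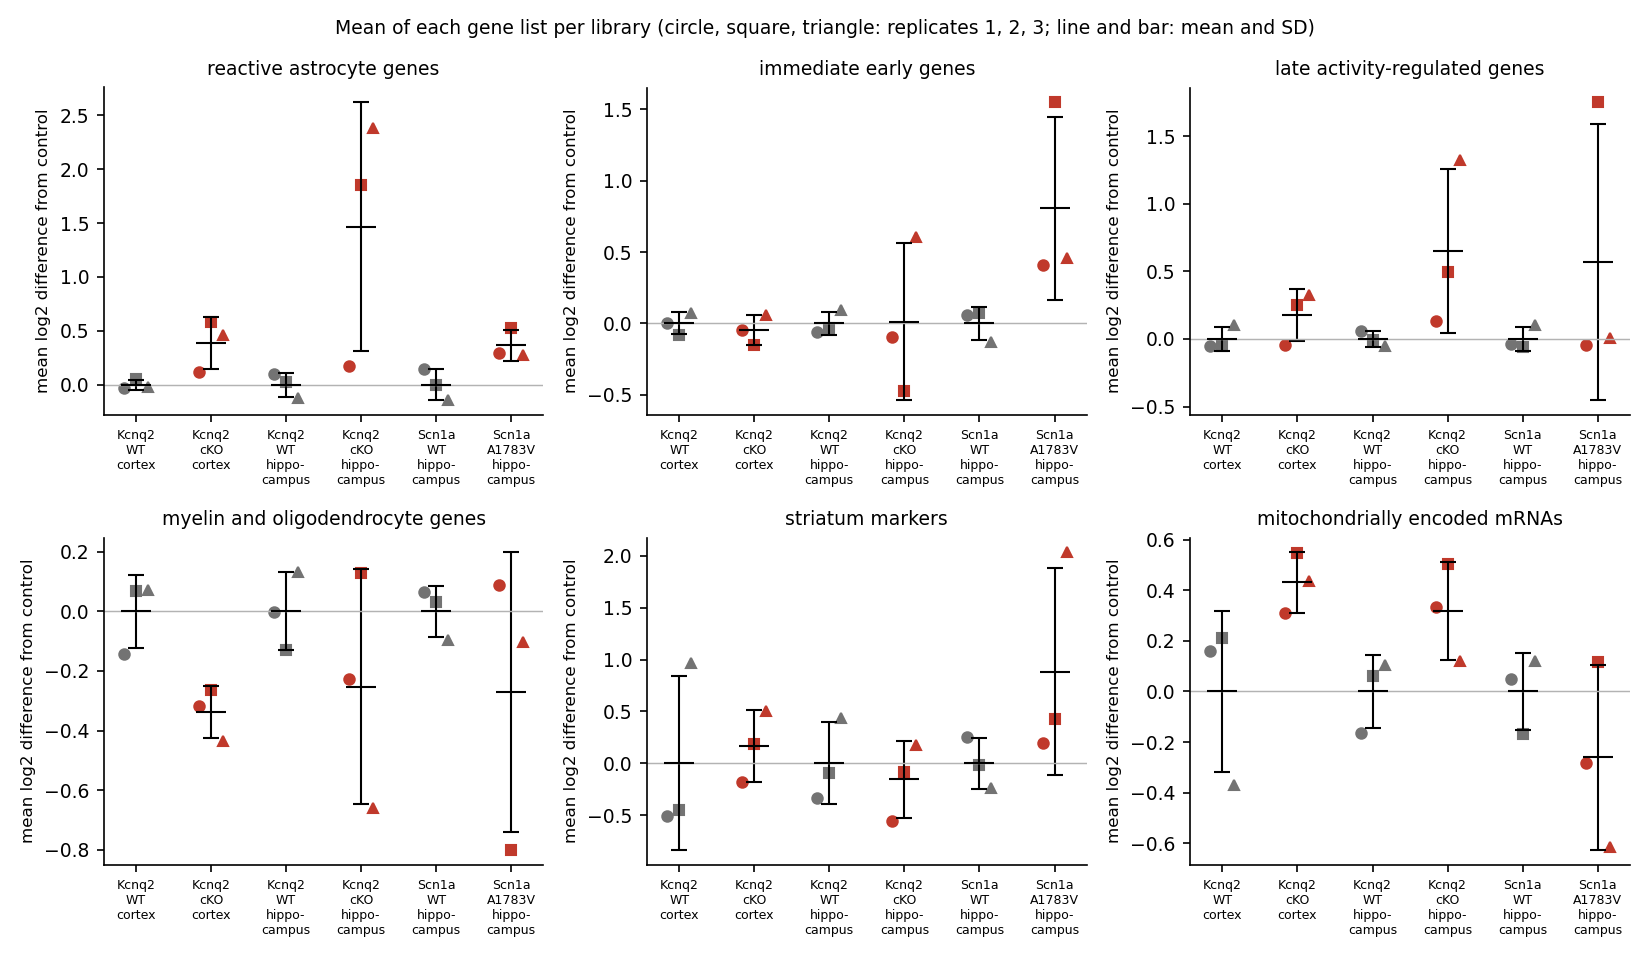
Mean log2 difference from the control mean of the same line and tissue (vertical axis) over the members of 6 gene lists, in each of the 18 libraries, by group; circles, squares and triangles are replicates 1, 2 and 3, and lines with bars are group means and SDs. Reactive astrocyte genes lay at 0.17, 1.85 and 2.38 in cKO hippocampus, immediate early genes at 0.41, 1.55 and 0.46 in A1783V hippocampus, and striatum markers at 2.03 in A1783V replicate 3.

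All 22 late activity-regulated genes were higher in cKO hippocampus, by a median of 0.51 (limma camera adjusted p = 7.4e-05; adjusted p = 0.670 with an estimated correlation). Bdnf measured 2.74 ± 0.441 in WT and 6.73 ± 2.85 in cKO, Inhba 0.489 ± 0.225 and 2.63 ± 2.32, and none passed over the list alone. The list mean was 1.32 in cKO replicate 3, 0.50 in replicate 2 and 0.14 in replicate 1, and without replicate 3 the call was lost at a median of 0.23 (limma adjusted p = 0.119). Immediate early genes had a median of −0.14 and a mean of 0.01.

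Neuropeptides were not called as a list (limma camera adjusted p = 0.0885), but 4 of 18 passed when adjusted over the list alone. Npy (chromosome 6, 49822710 to 49829507, plus strand) rose from 20.2 ± 2.75 to 86.3 ± 65.6, Gal by 2.59 and Trh by 3.42, and Cartpt fell by 1.58 (limma adjusted p = 0.0172, 0.0172, 0.0338 and 0.0172 adjusted over the list alone). The Gal, Trh and Cartpt calls were lost without 3, 4 and 2 of the 6 libraries in turn. Among the 17 GABA-A receptor and chloride transport genes, Gabrd (chromosome 4, 155384980 to 155398112, minus strand) fell from 5.06 ± 0.104 to 2.31 ± 0.960 and Gabrg1 from 5.72 ± 1.52 to 3.35 ± 0.433, both with limma adjusted p = 0.00402 adjusted over the list alone. Voltage-gated sodium channels fell by a median of 0.31 (limma camera adjusted p = 0.0488; adjusted p = 0.441 with an estimated correlation). Glutamate receptors fell by a median of 0.15 (limma camera adjusted p = 0.0432; adjusted p = 0.670 with an estimated correlation). Without scaling their median was 0.11, still below the 0.26 by which all genes then moved, and the call was lost. Dlx1 fell by 0.64 and Pex5l by 0.61 (limma adjusted p = 0.0220 and 0.00599 adjusted over the list alone).

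Choroid plexus and ependymal markers fell by a median of 0.73 (limma camera adjusted p = 7.4e-05; adjusted p = 0.670 with an estimated correlation), with 2 of 18 positive. Tmem212 fell by 1.44 and Ccdc153 by 1.16, both with limma adjusted p = 0.0373 adjusted over the list alone. Myelin genes fell by a median of 0.28 (limma camera adjusted p = 0.0018; adjusted p = 0.677 with an estimated correlation), with 3 of 26 positive and Opalin at −0.41. The 13 mitochondrially encoded mRNAs were all higher, by a median of 0.32 (limma camera adjusted p = 0.0017; adjusted p = 0.670 with an estimated correlation). Endothelial markers rose by 0.15, neurogenesis genes by 0.40 and unfolded protein response genes by 0.18 (limma camera adjusted p = 0.0498, 0.0498 and 0.0314; adjusted p = 0.670, 0.670 and 0.645 with an estimated correlation). Rgs5, Tnc, Timp1, Fn1 and Col3a1 rose by 0.55, 1.43, 2.82, 0.91 and 1.40, and Bcan fell by 0.46 (limma adjusted p = 0.0381, 0.0329, 0.0383, 0.0233, 0.0257 and 0.0383 adjusted over the list alone).

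The reactive astrocyte and choroid plexus calls held without any single hippocampus library, as did those of S100a10, Emp1, Serpina3n, Gfap, Npy, Gabrd and Gabrg1, while 14 of the 21 named genes lost their call without some library. The Npy difference fell from 1.76 to 1.16 without cKO replicate 2. With a library left out, medians came as close to 0 as −0.04 for glutamate receptors, −0.07 for myelin, 0.06 for endothelial markers and 0.20 for mitochondrial mRNAs. Lost calls were those of myelin without WT replicate 3 or cKO replicate 3 (limma adjusted p = 0.116 and 0.608), mitochondrial mRNAs without cKO replicate 2 (limma adjusted p = 0.0908), sodium channels, glutamate receptors and the unfolded protein response without WT replicate 3, cKO replicate 2 or cKO replicate 3 (limma adjusted p from 0.0509 to 0.284), endothelial markers without any of these 3 or WT replicate 2 (limma adjusted p from 0.0870 to 0.245), and neurogenesis without WT replicate 2, cKO replicate 1 or cKO replicate 2 (limma adjusted p from 0.0631 to 0.262).

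The Scn1a comparison asked what the A1783V allele in inhibitory neurons did to the hippocampus. Immediate early genes rose as a list, with Ier2, Npas4 and Egr4 among the members that rose when adjusted over the list alone. Voltage-gated calcium channel genes rose as a list, as did striatum markers, while myelin genes fell, the last 2 mainly in a single library each. The striatum direction turned with mt-Rnr2 as a covariate. None of these list calls held with an estimated correlation (smallest limma adjusted p = 0.400). The vasopressin gene Avp was higher in every A1783V library than in the controls.

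Limma called 3 genes of 15553, all higher in A1783V, each with limma adjusted p = 0.0387. Ube2o (chromosome 11, 116537740 to 116581447, minus strand) rose from 4.63 ± 0.369 to 7.79 ± 0.304 (log2 difference 0.74, SE 0.11). Anxa3 (chromosome 5, 96793339 to 96845966, plus strand) rose from 2.0 ± 0.439 to 4.35 ± 0.415 (log2 difference 1.10, SE 0.17). Avp (chromosome 2, 130580620 to 130582554, minus strand), named after its values were seen, was listed at 0, 0.0910 and 0 in the controls and at 7.71, 1.15 and 3.59 in A1783V, a rise for which no fold is given, since an exact 0 in these values does not show absence. Of 15 other settings, 6 ended the Avp call and 7 those of Ube2o and Anxa3. The Avp and Ube2o calls were lost without WT replicate 1, WT replicate 3 or A1783V replicate 3 (limma adjusted p = 0.143, 0.120 and 0.179), and the Anxa3 call without these or A1783V replicate 1 (limma adjusted p from 0.0523 to 0.183). At an unadjusted p under 0.05 in the fit of all 18 libraries, 1856 genes passed, 1195 higher and 661 lower, where chance gives 778. With the Scn1a libraries alone 849 genes passed, near that chance number, and limma called 0 (smallest adjusted p = 0.354). The larger count thus depends on the spread pooled over both lines. Fully separated libraries were found for 11.6% of genes, where chance gives 10%. The number of calls was 104 without A1783V replicate 2, 32 without WT replicate 2, 20 without A1783V replicate 1, and 0 without WT replicate 1 or A1783V replicate 3. Without scaling it was 1970, of which 1961 were higher, at a median shift of all genes of 0.32. Of the 38 lists 12 passed in camera, 7 up and 5 down, and 26 missed the threshold. With an estimated correlation 0 passed, and fry called 1 in 1 direction and 7 in either direction.

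Of 22 immediate early genes 21 were higher in A1783V, by a median of 0.80 (limma camera adjusted p = 1.9e-07; adjusted p = 0.726 with an estimated correlation). Adjusted over the list alone, 7 rose, and over all genes 0 did. Ier2 rose from 0.528 ± 0.0580 to 1.26 ± 0.287 (limma adjusted p = 0.00152 adjusted over the list alone), and Npas4 from 0.515 ± 0.0547 to 2.15 ± 1.84 and Egr4 from 0.364 ± 0.162 to 1.05 ± 0.134 (limma adjusted p = 0.00927 adjusted over the list alone). The list mean was 1.55 in A1783V replicate 2, 0.46 in replicate 3 and 0.41 in replicate 1, and without replicate 2 the median was 0.41 (limma adjusted p = 0.0323) and the Npas4 difference 0.94 in place of 1.57. Late activity-regulated genes rose by 0.55 (limma camera adjusted p = 0.0036; adjusted p = 0.726 with an estimated correlation), with a mean of 1.75 in replicate 2 and −0.04 and 0.00 in the others. Without replicate 2 that median was 0.03.

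Voltage-gated calcium channels rose by a median of 0.31, in 17 of 21 cases (limma camera adjusted p = 7.4e-04; adjusted p = 0.400 with an estimated correlation), and this was the list called by fry in 1 direction (limma adjusted p = 0.0229). Cacnb1 rose by 0.51, Cacng2 by 0.66 and Cacna1g by 0.69 (limma adjusted p = 0.0228 adjusted over the list alone). Epilepsy-linked channel and synapse genes rose by 0.19 (limma camera adjusted p = 0.0125; adjusted p = 0.726 with an estimated correlation), with Kcnb1, Grin1 and Dnm1 rising by 0.58, 0.56 and 0.38 (limma adjusted p = 0.00827, 0.0156 and 0.0360 adjusted over the list alone). Synaptic vesicle genes rose by 0.21 and glycolysis genes by 0.14 (limma camera adjusted p = 0.0170 and 0.0487; adjusted p = 0.726 with an estimated correlation), with Stx1b and Syt2 rising by 0.52 and 1.04 (limma adjusted p = 0.0437 adjusted over the list alone), calls that 8 of 15 other settings ended. The glycolysis call was lost in 10 of 15 other settings. In lists that were not called, Kcnh1, Grik5 and Grm4 rose by 0.66, 0.54 and 0.89, and the microglial gene Gpr34 fell by 0.76 (limma adjusted p = 0.0463, 0.0102, 0.0292 and 0.00826 adjusted over the list alone).

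Myelin genes fell by a median of 0.24, with 3 of 26 positive (limma camera adjusted p = 1.5e-05; adjusted p = 0.726 with an estimated correlation). Without A1783V replicate 2 the median was −0.02. Cholesterol synthesis genes fell by 0.09 (limma camera adjusted p = 0.0260; adjusted p = 0.726 with an estimated correlation), and Idi1 fell by 0.67 (limma adjusted p = 0.0368 adjusted over the list alone). Mitochondrially encoded mRNAs fell by 0.21 (limma camera adjusted p = 0.0049; adjusted p = 0.726 with an estimated correlation), and mt-Nd3 fell by 0.68 (limma adjusted p = 0.0329 adjusted over the list alone). Dentate gyrus markers fell by 0.30 (limma camera adjusted p = 0.0147; adjusted p = 0.726 with an estimated correlation). Without scaling, which moved all genes of this line up by a median of 0.32, these 4 medians turned to 0.07 for myelin, 0.23 for cholesterol synthesis, 0.11 for mitochondrial mRNAs and 0.0016 for dentate markers. All stayed below the other genes, and only the cholesterol call was lost. Calb1 fell by 0.74 and Pdzd2 rose by 0.81 (limma adjusted p = 0.0476 adjusted over the list alone), calls that 10 and 9 of 15 other settings ended. All 16 striatum markers were higher, by a median of 0.96 (limma camera adjusted p = 7.4e-04; adjusted p = 0.726 with an estimated correlation), with Penk at 2.13. Their mean was 2.03 in A1783V replicate 3, and without it the median was 0.23. With mt-Rnr2 as a covariate the striatum median turned to −0.52 and the mitochondrial mRNA median to 0.59. Choroid plexus markers fell by 0.37 (limma camera adjusted p = 0.0480; adjusted p = 0.749 with an estimated correlation), which turned to 0.20 without A1783V replicate 2.

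Reactive astrocyte genes in A1783V hippocampus had a median of 0.20, with 14 of 19 positive, and did not pass (limma camera adjusted p = 0.345). The immediate early and calcium channel calls held without any single Scn1a library, as did those of Ier2, Npas4 and Egr4, while 17 of the 20 named genes lost their call without some library. Lost calls were those of late activity genes and myelin without A1783V replicate 2 (limma adjusted p = 0.502 and 0.487), striatum markers, dentate markers and mitochondrial mRNAs without A1783V replicate 3 (limma adjusted p = 0.283, 0.0831 and 0.283), epilepsy-linked genes without WT replicate 1 or A1783V replicate 2 (limma adjusted p = 0.178 and 0.487), cholesterol synthesis without WT replicate 1, A1783V replicate 1 or A1783V replicate 2 (limma adjusted p from 0.0788 to 0.415), choroid plexus without WT replicate 1, WT replicate 2 or A1783V replicate 2 (limma adjusted p from 0.117 to 0.487), and synaptic vesicle and glycolysis genes without WT replicate 2, WT replicate 3 or A1783V replicate 2, glycolysis also without A1783V replicate 3 (limma adjusted p from 0.0981 to 0.636). With a library left out, medians came as close to 0 as 0.07 for synaptic vesicle and glycolysis genes, 0.11 for epilepsy-linked genes, −0.0077 for cholesterol synthesis and −0.010 for mitochondrial mRNAs.

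**Figure D3:**
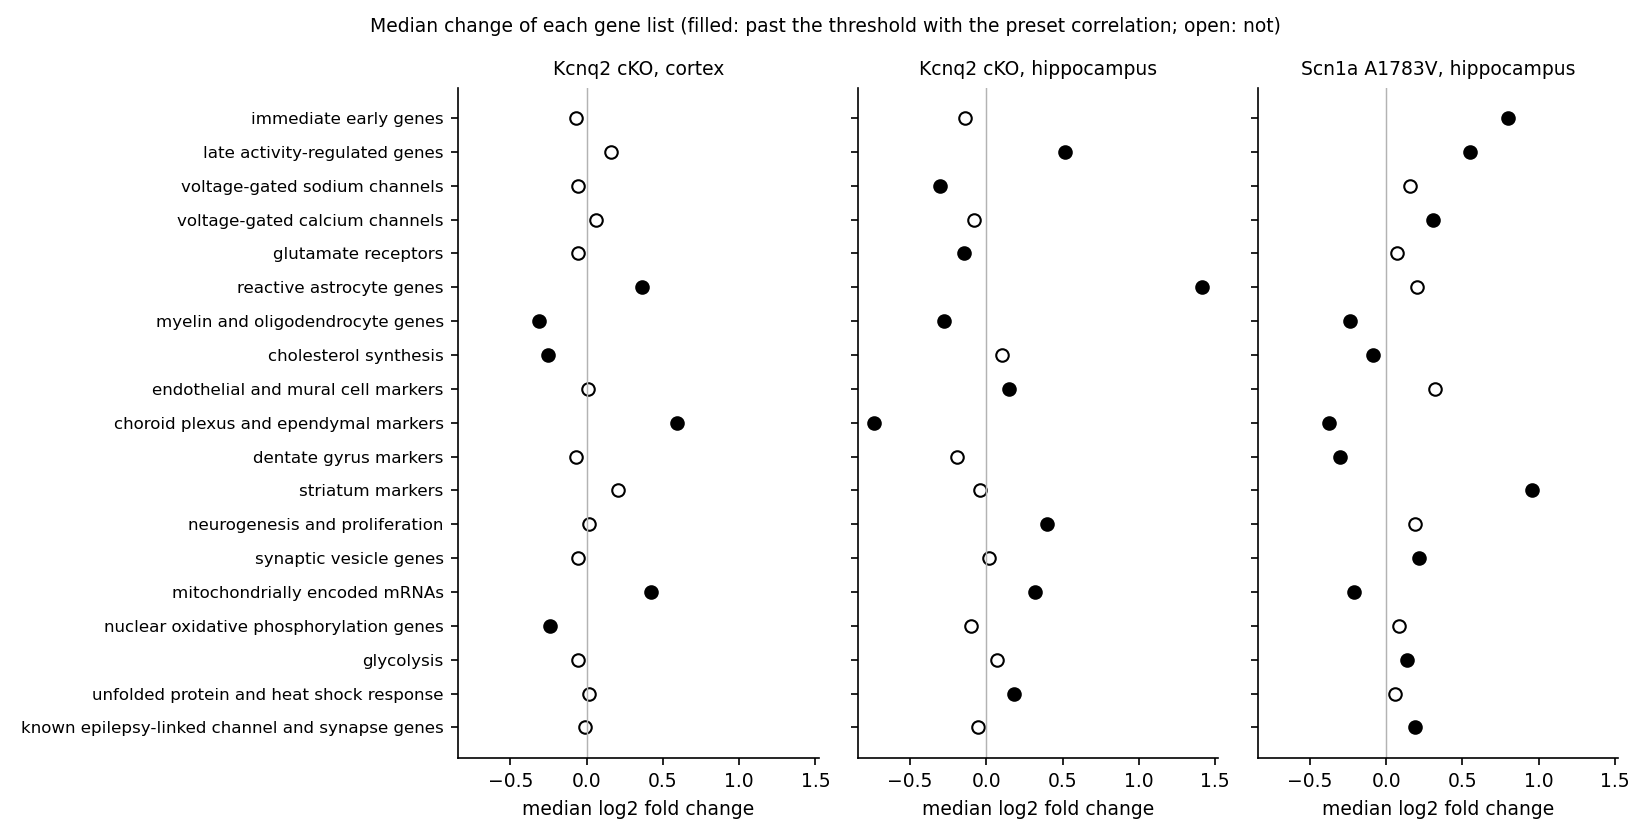
Median log2 fold change (horizontal axis) of the gene lists called in at least 1 comparison, with a panel for each comparison of mutant and control libraries; filled circles passed the threshold with the preset correlation and open circles did not. Reactive astrocyte genes lay at 0.36, 1.41 and 0.20 and myelin genes at −0.31, −0.28 and −0.24, the last of which turned to 0.07 without scaling, where all genes moved up by 0.32.

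The effects in the 2 tissues of the Kcnq2 line were positively correlated, more so than in any other labelling tried, and no correlation passed the test between lines with all libraries. In both tissues every cKO library also exceeded every control in fitted length offset, mt-Rnr2 share and scale factor. A library difference shared by the tissues therefore cannot be told apart from genotype here. The correlation was not refitted with mt-Rnr2 as a covariate. Across 15553 genes, which are not independent replicates, the cortex and hippocampus effects of Kcnq2 correlated with Pearson's r = 0.351 and Spearman's rho = 0.372. None of the other 99 labellings of the libraries reached this (highest 0.322), which gave the smallest permutation p they allow, 0.01, or 0.03 adjusted over the 3 pairs. Both tissues may come from the same mice, in which case this p does not measure independent mice. Relabelling within replicate numbers gave an exact permutation p of 0.0625, the smallest possible, which ended the call. With both tissues of a replicate number relabelled together, the other 9 splits gave r from 0.0315 to 0.175, for a permutation p of 0.10, also the smallest possible. Of 218 genes at an unadjusted p under 0.05 in both tissues, 74 were higher and 135 lower in both and 9 went opposite ways, where independent lists give 21.1, 31.2 and 52.4. The Kcnq2 and Scn1a effects in hippocampus correlated at −0.057 (rho = −0.0493, permutation p = 0.58), and of 180 shared genes 111 went opposite ways, where independent lists give 88.9. The Kcnq2 effect in cortex and the Scn1a effect correlated at −0.163 (rho = −0.194, permutation p = 0.16, adjusted 0.24; −0.25 and unadjusted p = 0.03 without Scn1a WT replicate 2), and of 184 shared genes 158 went opposite ways, where independent lists give 68.8.

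The difference between tissues of the Kcnq2 line asked whether cortex and hippocampus responded alike. Reactive astrocyte and late activity-regulated genes differed as lists, with the smaller effect in cortex, and choroid plexus markers differed the other way. No list call held with an estimated correlation (smallest limma adjusted p = 0.267), and the late activity call was lost without cKO hippocampus replicate 3. Over single genes limma called 0 (smallest adjusted p = 0.476), with 356 genes at an unadjusted p under 0.05, fewer than the 778 that chance gives. This fit takes all libraries as independent, and with the replicate number as a block limma called 1 gene (adjusted p = 0.0118), with 636 at an unadjusted p under 0.05. Camera called 8 lists, 2 up and 6 down, with 0 called by fry or with an estimated correlation. Reactive astrocyte genes differed by −1.26 (limma camera adjusted p = 2.1e-10; adjusted p = 0.486 with an estimated correlation), with S100a10 at −2.08 (limma adjusted p = 0.0265 adjusted over the list alone). Choroid plexus markers differed by 1.28 (limma camera adjusted p = 6.8e-12; adjusted p = 0.486 with an estimated correlation) and cholesterol synthesis genes by −0.34 (limma camera adjusted p = 5.5e-07; adjusted p = 0.486 with an estimated correlation). These 3 held without any single library, but the reactive astrocyte difference fell to −0.73 without cKO hippocampus replicate 3 and the cholesterol difference to −0.20 without WT cortex replicate 3. Late activity-regulated genes differed by −0.46 (limma camera adjusted p = 0.00129; adjusted p = 0.834 with an estimated correlation), a call lost at −0.16 without cKO hippocampus replicate 3.

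The difference between lines asked whether the potassium channel and sodium channel mutants shared a hippocampal response. Reactive astrocyte genes were higher in the Kcnq2 effect, and immediate early and calcium channel genes were higher in the Scn1a effect, all as lists. No list call held with an estimated correlation (smallest limma adjusted p = 0.614), and the immediate early call was lost without A1783V replicate 2. The lines also differed in library composition, which this comparison cannot remove. Limma called 0 genes (smallest adjusted p = 0.174), with 1977 at an unadjusted p under 0.05, and camera called 7 lists, 3 up and 4 down, with 0 called with an estimated correlation, and 0 in 1 direction and 8 in either direction by fry. Reactive astrocyte genes differed by 1.18 (limma camera adjusted p = 1.3e-06; adjusted p = 0.671 with an estimated correlation), in all 19 cases, and by 0.61 without cKO replicate 3 and 1.85 without cKO replicate 1. Immediate early genes differed by −0.91 (limma camera adjusted p = 7.3e-05; adjusted p = 0.671 with an estimated correlation), with Npas4 at −2.29 and Ier2 at −1.22 (limma adjusted p = 0.00847 adjusted over the list alone), and this list's call was lost at −0.59 without A1783V replicate 2 (limma adjusted p = 0.0781). Calcium channels differed by −0.39 (limma camera adjusted p = 0.00249; adjusted p = 0.614 with an estimated correlation). Gabrd differed by −1.64, Kcnb1 by −0.75 and Idi1 by 1.10 (limma adjusted p = 0.00982, 0.00982 and 0.0108 adjusted over the list alone).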

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

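The tests of tissue admixture, astrocyte share, striatal tissue, a single animal, sex, fragment length, transcript length and mt-Rnr2 were applied to these patterns only after the data were seen, while leaving out single libraries and the counts of other splits were set before. All results below came up because a test of the difference itself, between tissues of the Kcnq2 line or between lines in hippocampus, passed in limma's camera with its preset correlation. None passed with an estimated correlation. The other splits of the samples did not exclude chance for either set: 48 of 100 splits gave at least the 8 lists called between tissues (highest other 15), and 79 of 100 gave at least the 7 called between lines (highest other 20).

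Reactive astrocyte genes responded more in cKO hippocampus than in cKO cortex, with a difference of −1.26 (cortex minus hippocampus), and more than in A1783V hippocampus, with a difference of 1.18. Several technical explanations of the rise in cKO hippocampus were argued against by the tables. Removing each library's trend on transcript length kept 99.03% of the list's median. Markers of meninges, vessels and choroid plexus had medians of at most 0.15 in the same libraries, below the 1.41 of the reactive genes (interval 1.07 to 1.76). That interval takes genes as replicates and leaves out the spread between mice. These medians argued against such tissue as the whole source of the rise. A part was not excluded, since Col3a1 and Rgs5 rose and the endothelial list was called. A larger share of astrocytes would raise astrocyte markers alike if their level per cell stayed the same, and their median was −0.088. This argued against a larger share only on that condition, which was not tested. A reactive state of hippocampal astrocytes in mice labelled cKO may be put forward only as a hypothesis, since it was not tested separately. The values per gene also did not check the cKO labels. It stays open why cKO replicate 1 lay at 0.17, and another split of the 6 libraries reached a list mean of 1.42 beside the real 1.47.

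Immediate early genes separated the lines, with a difference of −0.91 (Kcnq2 effect minus Scn1a effect), since they rose in A1783V hippocampus and had a median of −0.14 in cKO hippocampus. Striatal tissue in the dissection was argued against only as the main source. A1783V replicate 3, where striatum markers were highest, had a lower immediate early mean than replicate 2. Without replicate 3 the list kept 120.6% of its median, which follows from that lower mean and adds no further evidence. A smaller striatal part was not excluded. Ddx3y was present (scaled TPM over 1) in 1 of 3 libraries of either group, at 19.9 in WT replicate 3 and 24.6 in A1783V replicate 2. An effect of sex equal in both groups would thus add alike to both means, which argued against it as the source. Without these 2 libraries 35.0% of the median was left (limma adjusted p = 0.0847), but this also removes A1783V replicate 2. An effect of sex in the mutants alone stayed open and cannot be told apart from a single animal here, since A1783V replicate 2 was the mutant with Ddx3y. Xist as a covariate left the list called (0.78), but that library's Xist level was intermediate, so this fit does not settle it. One animal with high activity genes could not be excluded as the source of most of the rise. Without A1783V replicate 2, 48.8% of the median was left (limma adjusted p = 0.0323), and the difference between lines was no longer called (−0.59). Whether that mouse had recently had a seizure is not given by the labels.

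Nuclear oxidative phosphorylation genes fell in cKO cortex while mitochondrially encoded mRNAs rose, and the first differed between tissues by −0.13. Transcript length was argued against as the whole cause, since 92.8% of the nuclear median and 104.8% of the mitochondrial median were kept without the length trend. Fragment length and genotype cannot be told apart for the nuclear genes, because all 3 cKO cortex libraries had a longer fitted length offset than every control. The ribosomal RNA mt-Rnr2 was also higher in all 3 cKO cortex libraries than in every control. With it as a covariate the mitochondrial median was 0.15 and the nuclear median −0.13, both still called. A change in respiratory gene expression is the open biological alternative and was not tested separately. Leaving out WT cortex replicate 3 ended the difference between tissues (−0.05, limma adjusted p = 0.165), as did mt-Rnr2 as a covariate (−0.055, limma adjusted p = 0.124).

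Between tissues of the Kcnq2 line, choroid plexus and ependymal markers differed by 1.28, with a rise in cortex and a fall in hippocampus. Another split of the cortex libraries reached a list mean of 0.87 in absolute size, beside the real 0.55 (exact permutation p = 0.3). The cortex rise was thus not set apart from chance. In hippocampus the highest other was 0.42, beside the real −0.71 (exact permutation p = 0.1, the smallest that 3 against 3 allow). Cholesterol synthesis genes differed by −0.34, with a list mean of −0.19 in cortex and 0.076 in hippocampus (exact permutation p = 0.3 and 0.4). Another split of the cortex libraries reached 0.27 in absolute size, so the cortex fall was not set apart from chance. Late activity-regulated genes differed by −0.46, a call that was lost without cKO hippocampus replicate 3. Thalamus markers differed by 0.33 (limma camera adjusted p = 0.0165), led by Prkcd at 1.26, and this call was lost without cKO cortex replicate 3 or WT hippocampus replicate 3 (0.24 and 0.15), and with the replicate block (limma adjusted p = 0.0680). Neurogenesis genes differed by −0.28 and unfolded protein response genes by −0.18 (limma camera adjusted p = 0.0393 and 0.0428). The neurogenesis call was lost without WT cortex replicate 3, cKO cortex replicate 2 or 3, WT hippocampus replicate 2, or cKO hippocampus replicate 1 or 2 (−0.17 to −0.42). The unfolded protein call was lost without WT cortex replicate 3, cKO cortex replicate 1, WT hippocampus replicate 2 or 3, or cKO hippocampus replicate 3 (−0.16 to −0.19).

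Between lines in hippocampus, voltage-gated calcium channel genes differed by −0.39, from a rise in A1783V. Mitochondrially encoded mRNAs differed by 0.47, with opposite directions in the lines, which did not hold with mt-Rnr2 as a covariate (0.59 in the Scn1a line and a difference of −0.32). Striatum markers differed by −0.88, a call lost at −0.27 without A1783V replicate 3. Epilepsy-linked channel and synapse genes differed by −0.25, a call lost without Kcnq2 WT replicate 3, Scn1a WT replicate 1 or A1783V replicate 2 (−0.20, −0.20 and −0.19). Cholesterol synthesis genes differed by 0.20, a call lost without Kcnq2 WT replicate 1, Scn1a WT replicate 1 or A1783V replicate 2 (0.17, 0.13 and 0.16).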

How the results depend on the processing

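The alternatives chosen only after the data were seen were the pseudocounts, unscaled values, small RNA left out, the length trend and mt-Rnr2 as a covariate. Where a value below moved, the cause was not tested unless it is named.

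The genes called in cortex numbered 3 with no filter, 14 with the libraries of the comparison alone, 0 with mt-Rnr2 as a covariate, and 0 to 2 with a library left out, beside the reported 1. Those in Kcnq2 hippocampus numbered 12 with the libraries alone and 0 to 198 with a library left out, beside 0. Those in the Scn1a line numbered 1 with median-of-ratios factors, 0 with Xist as a covariate, 0 with the libraries alone, 0 with pseudocount 0.01, 10 with pseudocount 1, 1970 unscaled, 0 with mt-Rnr2 and 0 to 104 with a library left out, beside 3. The unscaled count follows from a shift of all genes by a median of 0.32 in this line, 0.20 in cortex and 0.26 in Kcnq2 hippocampus. The difference between tissues gave 3 with the libraries alone and 0 to 12 with a library left out, beside 0. The difference between lines gave 1 with no filter, 1 with the libraries alone and 0 to 117 with a library left out, beside 0.

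The lists called fell to 0 in each of the 5 comparisons with an estimated correlation. With fry they fell to 0 in all but the Scn1a comparison, where 1 was called. By construction, an estimated correlation widens the error of lists whose members vary together, and fry compares a list with no change instead of with other genes. With mt-Rnr2 as a covariate there were 10 in cortex beside 6, and 18 for the difference between lines beside 7. With structural RNA left out there were 6 in Kcnq2 hippocampus beside 10. With a library left out they ranged from 4 to 6 in cortex, 4 to 14 in Kcnq2 hippocampus, 6 to 17 in the Scn1a line, 7 to 10 between tissues and 5 to 13 between lines.

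Directions turned for a few lists. Unscaled, the medians were 0.11 for glutamate receptors in Kcnq2 hippocampus, and 0.072 for myelin, 0.23 for cholesterol synthesis, 0.0016 for dentate gyrus markers and 0.11 for mitochondrially encoded mRNAs in the Scn1a line, each below the shift of all genes in its comparison. With mt-Rnr2 as a covariate, striatum markers turned to −0.52 and mitochondrially encoded mRNAs to 0.59 in the Scn1a line, and to 0.60 and −0.32 between lines. Without A1783V replicate 2, choroid plexus markers of the Scn1a line turned to 0.20 and Kcne2 to 0.081, in ranges that began at −0.90 and −1.30 without A1783V replicate 1.

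Of the targeted genes, Kcnq2 in the Scn1a line reached 0.58 unscaled and passed (limma adjusted p = 0.0140, in a range of 0.0140 to 0.892 over alternatives), which includes that line's shift. With a library left out its difference ranged from 0.19 to 0.36 there, from 0.07 to 0.15 in cortex and from 0.27 to 0.37 in Kcnq2 hippocampus. That of Scn1a ranged from −0.11, reversed without WT replicate 1, to 0.35 in its own line, from −0.30 to −0.19 in cortex and from −0.42 to −0.17 in Kcnq2 hippocampus. The correlation of Kcnq2 effects between tissues ranged from 0.26 with no filter to 0.45 with pseudocount 1, and from 0.27 to 0.39 with a library left out. That of hippocampal effects between lines turned to 0.0068 with small RNA left out, and ranged from −0.12 to 0.010, reversed to 0.0060 without cKO hippocampus replicate 1 and 0.010 without Scn1a WT replicate 1. That of Kcnq2 cortex with the Scn1a line ranged from −0.063 to −0.25, the last without Scn1a WT replicate 2, where it passed (permutation p = 0.03).

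Deviations did not pair control and mutant libraries by replicate number, while Ddx3y and Xist agreed between cortex and hippocampus by number without establishing that a number is 1 mouse. Deviations of control and mutant libraries with the same number correlated at −0.0596 to −0.0136 in cortex, −0.0888 to −0.0231 in Kcnq2 hippocampus and −0.245 to 0.0213 in the Scn1a line, and those of cortex and hippocampus at −0.0161 to 0.109, with 1 of 6 over 0.1. With the replicate block there were 0 genes called in cortex, 2 in Kcnq2 hippocampus, 0 in the Scn1a line, 1 between tissues and 0 between lines. The block left the correlation between tissues at 0.351, with an exact permutation p of 0.0625, the smallest that relabelling within pairs allows.

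Over all list results, 578 of 641 values under alternatives kept direction and call, 54 lost the call and 9 reversed. With a library left out, 278 of 348 kept both, 69 lost the call and 1 reversed. Of 1299 values for single genes 1104 kept both, 183 lost the call and 12 gained it, and with a library left out 398 of 564 kept both, 153 lost the call, 12 gained it and 1 reversed. In cortex the reactive astrocyte and choroid plexus calls were lost with pseudocount 0.5 or 1 and unscaled, and choroid plexus also with the libraries of the comparison alone (0.59, limma adjusted p = 0.0722). In the Scn1a line glycolysis lost its call in 10 of 15 settings and choroid plexus markers in 6 of 15, and in Kcnq2 hippocampus endothelial and neurogenesis markers in 7 each and sodium channels in 3. Between tissues the unfolded protein response lost its call in 5 of 15.

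The planned second count test was not run, because the deposited unit holds no counts, and the correlation over genes past the threshold gave no value, since the comparisons had too few such genes. The simulated data showed that changes of 1.5-fold are mostly missed with 3 libraries per group.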

Other observations

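The tests of a rise shared by the mutants and of the structure behind other splits were chosen only after the results were seen, while those of alleles near the targeted loci and the counts of other splits were set before.

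Myelin genes had a negative median in each comparison of mutant and control libraries, −0.31 in cKO cortex, −0.28 in cKO hippocampus and −0.24 in A1783V hippocampus. In the Scn1a line this came from 1 library: the list mean was −0.80 in A1783V replicate 2, and 0.09 and −0.10 in the others. In cKO hippocampus it was −0.66 in replicate 3, −0.23 in replicate 1 and 0.13 in replicate 2, whereas in cKO cortex all 3 libraries lay between −0.26 and −0.43. The same A1783V replicate 2 had the lowest means of choroid plexus markers (−1.43) and leptomeningeal markers (−1.39).

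Avp was not alone among genes of magnocellular neurons. Oxt, chosen after its values were seen, was listed at 0 in all 3 controls of the Scn1a line and at 1.42, 0 and 0.72 in the A1783V libraries. An exact 0 in these values does not show absence, and the source of either transcript was not tested.

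Reactive astrocyte genes were higher on average in the mutants of all comparisons, with list means of 0.38, 1.47 and 0.36. With replicate numbers taken as mice and relabelled within each line, a mean over the 3 comparisons as large as the real 0.74 arose only in the real labelling, for a permutation p of 0.005, the smallest that 400 labellings allow. Adjusted over the 38 lists this was 0.19, the least that 1 list alone at that p could reach, so the adjusted value decides nothing. The mean also does not test whether the comparisons share a rise. Its largest part came from cKO hippocampus, and the list did not pass in the Scn1a line. A shared rise may be considered only as a hypothesis for other mice.

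Alleles that travelled with the targeted loci could produce differences near them. Within 20 Mb of Scn1a or Slc32a1, 21 of 477 genes passed an unadjusted p of 0.01 in the Scn1a line, against 530 of 15076 elsewhere, an odds ratio of 1.26 (95% interval 0.768 to 1.98, Fisher's exact test). The upper bound argued only against a large excess of such genes near these loci. A linked change of a few genes would hardly move this ratio and was not excluded. Near Emx1 in the Kcnq2 line the odds ratio was 1.23 (95% interval 0.579 to 2.32), too wide to decide. Genes near Kcnq2 itself were not tested in this way.

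Other splits of the same libraries were too few for a share under 0.05 in the comparisons of 3 with 3. In cortex 2 of 10 splits gave at least the real 1 gene (highest other 1), and 6 of 10 at least the real 6 lists (highest other 10). In Kcnq2 hippocampus 3 of 10 gave at least 10 lists (highest other 14). In the Scn1a line 3 of 10 gave at least 3 genes (highest other 348), and 5 of 10 at least 12 lists (highest other 16). Where the real count was 0 genes every split had to match it, so 10 of 10 in Kcnq2 hippocampus (highest other 10), 100 of 100 between tissues (highest other 2) and 100 of 100 between lines (highest other 26) say nothing about chance.

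The 348 genes point to a structure of the Scn1a samples that crosses genotype, as do the 26 between lines. That split set WT replicates 1 and 3 and A1783V replicate 2 against WT replicate 2 and A1783V replicates 1 and 3. The mitochondrial ribosomal RNA mt-Rnr2 took 8.83, 10.6 and 7.96% of the TPM in the first 3 libraries and 6.95, 5.65 and 4.88% in the second 3. Ddx3y was over a scaled TPM of 1 in 2 of the first 3 and in none of the second 3. Refitted with mt-Rnr2 as a covariate this split called 13 genes, and with Ddx3y over 1 as a covariate 35. Both covariates overlap with the split, mt-Rnr2 fully, so calls would be lost whatever the cause. RNA preparation and sex both stay open.

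Libraries of the Kcnq2 line differed in the length offset fitted to their low values, which follows the mean fragment length. It was 178 to 188 bases in the 6 cKO libraries and 168 to 176 in the 6 controls. Averaged over the tissues of each replicate number the difference was 9.67 bases, with an exact permutation p of 0.1, the smallest that 3 against 3 allow.

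Xist, which is transcribed from an inactive X chromosome, was present beside the Y-linked Ddx3y in some libraries. Kcnq2 WT replicate 2 held 7.51% of the Xist level of libraries with Ddx3y under a scaled TPM of 1 in cortex and 8.07% in hippocampus, and A1783V replicate 2 held 11.3%. The other libraries with Ddx3y over 1 held at most 0.438%. In the Kcnq2 line whether Ddx3y was over 1 agreed between cortex and hippocampus for each genotype and replicate number.

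Rny1 was listed at 0 in cKO cortex replicates 2 and 3 and cKO hippocampus replicate 1, and took 3.81 to 18.7% of the TPM in the other 15 libraries, so an exact 0 in these values may be a failed estimate. With small RNA left out, the effects of the lines in hippocampus correlated at 0.0068 in place of −0.057.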
